A study of Caenorhabditis elegans with 11 samples.

How the data were processed

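Poly(A)+ RNA was sequenced from 11 samples of young adult C. elegans in 4 groups, soma control (2), soma-depleted (3), germline control (3) and germline-depleted (3), per the labels. The labels describe 3 biological replicates; the soma control samples analysed here are replicates 1 and 3. Gene identifiers follow Ensembl 97 and splicing events use StringTie gene models, per the file headers. Per the submitters' processing notes, the tools were Trim Galore 0.6.0, cutadapt 1.18, STAR 2.7.2a, SAMtools 1.7 and DESeq2 1.26.0, with the genome build WBcel235/ce11. The read counter and the splicing caller are not given in the sources used here.

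The authors deposited a table of expression with group mean FPKM values (fragments scaled by transcript length and library size), which pool replicates and are normalized per the file headers. The same table holds the authors' log2 fold changes and Benjamini-Hochberg adjusted p-values, and the authors' mean count over all samples, whose normalization is not given in the sources used here. The log2 fold changes lay within 0.1 of the log2 ratio of depleted to control FPKM within a tissue for 880 of 882 genes in the soma and 882 of 882 in the germline. They are therefore read as depleted over control within each tissue, although the header note words the germline column as set against the soma control. The authors deposited a second table of 3096 splicing events with false discovery rate q-values and inclusion level differences, per the file headers. All 3096 events had a q-value under 0.05 in the soma, the germline or a comparison of sperm-producing with oocyte-producing worms from another study that the authors processed alongside. Listed event starts count from 0, since the start plus 1 matched an annotated exon start for 2396 events and the start itself for 10; coordinates are given here counted from 1.

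The tables list only genes and events that passed a threshold, as group means. No count model could be fitted, depth per sample is unknown, and no standard error or leave-out check could be computed. Fold changes and adjusted p-values are therefore the authors' own, and a group mean with pooled replicates hides how far the replicates lie apart. Selection on a fold change also inflates the size of listed changes.

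Genes with an adjusted p under 0.05 and events with a q-value under 0.05 were counted by direction, with an exact two-sided binomial test against an even split. For 23 gene lists fixed before the data were examined, the split of higher and lower among called members was compared with the other called genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists with called members (12 in each comparison). An adjustment over a list alone needs unadjusted p-values, which are not used here. The binomial and Fisher's exact tests count each gene or event as independent, although list members can move together or share reads. Their p-values can thus be too small and do not measure the spread between replicates. Event types were compared between tissues by Fisher's exact tests adjusted over 5 types, and by 100000 permutations for all types together. Genes and strands were taken from the Ensembl release 115 annotation of the same assembly, which held 881 of the 882 gene identifiers. A strand could be taken from the named gene for 2717 of 3096 events. For A3SS and A5SS events, the nearest annotated exon that is shorter at the alternative edge and shares the other edge gave the distance between sites. Bases at splice sites were not analysed here.

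Named genes followed a rule fixed before the data were examined. It took the 10 largest log2 fold changes in each direction among called genes with a mean count of at least 10, up to 4 called members per list with the smallest adjusted p, and up to 10 genes called in both comparisons, by the larger of their adjusted p-values. For splicing it took up to 3 events per type and tissue with the largest absolute difference and up to 5 shared events with the largest mean absolute difference. Genes named outside the rule are said to be so. Alternatives were a threshold of 0.01, minimum log2 fold changes of 1 and 2, mean counts of at least 10 and 100, protein-coding genes, minimum inclusion differences of 0.2 and 0.3, and an event counted once per gene. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The list test was tested on simulated data: planted lists of 15 genes that all moved one way were called in 100% of cases among 525 soma genes and 97.5% among 555 germline genes, and unplanted lists in 0.5% and 0.556%. Simulated even splits of 1606 and 796 events were called in 6.7% and 3.9% of cases, and splits of 0.6 in 100%. Genes and events moved independently in these simulations, as the tests assume. The simulations therefore check the computation, not the rate of false calls among real lists, whose members can move together or share reads.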

Results

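SACY-1 is the C. elegans ortholog of the human helicase DDX41, a protein of the spliceosome. Worms carried SACY-1 with an auxin-inducible degron tag together with TIR1, the plant receptor that directs tagged proteins to degradation when auxin is present. TIR1 was expressed either in somatic cells, from the eft-3 promoter, or in the germline, from the gld-1 promoter. Control strains carried the same TIR1 transgene without the tagged protein. All young adults received 2 mM auxin for 24 hours at 20 °C, and poly(A)+ RNA from lysates of the worms was sequenced. The words soma and germline thus name where SACY-1 was depleted, not a tissue that was isolated. Transcripts of any tissue can appear in either comparison. Below, differences between tissues are differences between these comparisons. The 11 samples comprised 2 soma controls, 3 soma-depleted samples, 3 germline controls and 3 germline-depleted samples. The values used here are the authors' group means and comparisons, so the depth of each sample is unknown, and no value has a standard deviation or replicate spread. In the authors' deposited table of expression, the mean count over all samples ranged from 25.3 to 72951 among 882 listed genes, with a median of 162. Each of the 882 genes had an adjusted p under 0.05 and an absolute log2 fold change of at least 1 in the soma or the germline comparison. A transcript of sacy-1 itself was not among these genes; depletion acts on the protein, so this does not check it.

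The first comparison asked which transcripts differed when SACY-1 was depleted from the soma. A xenobiotic transporter, a glutathione transferase and a pair of metal-responsive genes were higher, as were the called genes of the sperm and heat-shock lists. Collagens of the cuticle, the extracellular coat of the worm, held 8 of the 10 largest decreases, although more called cuticle genes were higher than lower. In the soma comparison, 525 genes had an adjusted p under 0.05 in the authors' deposited table, 262 higher and 263 lower (49.9% higher, exact two-sided binomial p = 1). At an absolute log2 fold change of at least 1, there were 484 genes, 242 in each direction. Genes under this fold change are listed only where the other tissue passed, so the 525 are not all the genes that passed on p alone.

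The largest increase in the authors' deposited table was that of pgp-8, a P-glycoprotein transporter on chromosome X at 10859301 to 10864422, from a mean of 0.348 to 7.69 FPKM (log2 fold change 4.47, DESeq2 adjusted p = 5.2e-73). The glutathione S-transferase gene gst-24 (chromosome II, 13610443 to 13611366) went from 13.7 to 181 FPKM in the authors' deposited table, with a log2 fold change of 3.72 and an adjusted p of 1.9e-121. The metal-responsive genes numr-2 and numr-1, near-identical copies that can share reads, had log2 fold changes of 3.41 and 3.26 in the authors' deposited table. F19B10.13 (4.05), F08G2.5 (3.35), the C-type lectin gene clec-174 (3.28), F10A3.1 (3.23), the collagen gene col-129 (3.18) and egas-3 (3.07), of the degenerin channel family, completed the 10 largest log2 fold changes in the authors' deposited table.

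Among the 55 called genes of the cuticle list, 33 were higher and 22 lower, a split whose difference from the other called genes did not pass (Fisher's exact p = 0.119, adjusted p = 0.247 over 12 lists). The median log2 fold change of the 55 genes was 1.20 in the authors' deposited table, with col-129 the largest of the higher members. The lower members included dpy-8 (log2 fold change -4.15), dpy-9 (-4.12), col-128 (-3.96), rol-6 (-3.72), sqt-2 (-3.69), sqt-1 (-3.66), col-41 (-3.58) and col-17 (-3.53) in the authors' deposited table. For dpy-9 (chromosome IV, 257403 to 259204) the authors' deposited table gave 20.3 FPKM in controls and 1.16 after soma depletion, against 75.8 and 56.4 FPKM in the germline control and germline-depleted groups. For col-41 it gave 6.95 and 0.587 FPKM, against 70.9 and 34.2. All of these collagens had a soma control mean below both germline means. Their germline log2 fold changes were also negative, from -0.34 for col-128 to -1.05 for col-41. All but those of col-128 and sqt-2 passed in the germline comparison. Y52B11B.1 (-3.97) and T26E4.4 (-3.87) were the other genes among the 10 largest negative log2 fold changes in the authors' deposited table.

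All 19 called genes of the sperm list were higher after soma depletion (Fisher's exact p = 1.3e-06, adjusted p = 1.6e-05 over 12 lists). They included sss-1 (log2 fold change 2.15), the paternal factor gene spe-11 (2.04), the major sperm protein gene msp-55 (2.35) and nspd-1 (1.51) in the authors' deposited table. Their levels were low, with a median over the 19 genes of 1.95 FPKM in controls and 6.26 FPKM after depletion, against 2.07 and 3.81 FPKM in the germline control and germline-depleted groups, in the authors' deposited table. The msp and nspd genes are near-identical copies, so counts of single members are uncertain, and the list test counts them as independent. All 9 called genes of the heat-shock list were higher too (Fisher's exact p = 0.00179, adjusted p = 0.0107 over 12 lists). For the small heat-shock protein genes hsp-16.41 and hsp-16.2 the log2 fold changes were 1.62 and 1.53 in the authors' deposited table, and for hsp-16.49 and F44E5.5 they were 1.40 and 1.41. The median of the 9 genes was 16.3 FPKM in soma controls, the lowest of the 4 groups, and 36.6 after soma depletion, against 127 and 32.8 in the germline control and germline-depleted groups, in the authors' deposited table.

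Of 15 called neuropeptide and insulin genes, 3 were higher and 12 lower, which did not pass after adjustment (Fisher's exact p = 0.0327, adjusted p = 0.131). The insulin-like genes ins-33 (log2 fold change -2.01) and ins-24 (-1.51) and the neuropeptide genes nlp-39 (-1.39) and nlp-80 (-1.08) were lower in the authors' deposited table. Of 24 called innate immunity genes, 7 were higher and 17 lower (Fisher's exact p = 0.0580, adjusted p = 0.174). The authors' deposited table gave clec-52 a log2 fold change of 1.49, clec-54 of -1.36 and the saposin-like gene spp-18 of -1.15. Of 16 called detoxification genes, 9 were higher and 7 lower (Fisher's exact p = 0.623, adjusted p = 0.748). Besides pgp-8 and gst-24, this list held the metallothionein gene mtl-2, with a log2 fold change of 1.06, and sdz-24, with -1.39, in the authors' deposited table. The sdz genes are named for embryonic transcription that needs the regulator SKN-1, not for detoxification as such. The metallothionein gene mtl-2 was also the only called gene of the intestine list (Fisher's exact p = 0.499, adjusted p = 0.665). The fatty acid desaturase gene fat-7 (log2 fold change 1.08), the acyl-CoA dehydrogenase gene acdh-2 (1.68) and the acetyl-CoA carboxylase gene pod-2 (35.5 to 80.5 FPKM) were the 3 called lipid genes, all higher in the authors' deposited table (Fisher's exact p = 0.124, adjusted p = 0.247).

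Other lists had few called genes in the soma or none listed. The F-box and MATH list had 10 called genes, 5 in each direction, among them fbxa-189 (log2 fold change 1.21), btb-17 (1.28), fbxa-163 (1.86) and skr-5 (-1.03) in the authors' deposited table. The vitellogenin vit-3 (1.38) and the strain marker unc-119 (1.35) were higher in the authors' deposited table. The control strains carry the unc-119(ed3) mutation and the depleted strains do not list it, so strain genotype and depletion differ together in every comparison. The intracellular pathogen response genes C53A5.9 and skr-5 went in opposite directions, with log2 fold changes of 1.14 and -1.03 in the authors' deposited table. No gene of 9 lists, which covered sacy-1 itself, oocyte and germline genes, endoplasmic reticulum stress, mitochondrial stress, ribosomal proteins, the spliceosome, RNA surveillance, small RNA pathways and muscle, was among the 882 listed. As the table holds no unchanged genes, this count cannot be set against a background.

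The second comparison asked the same of depletion from the germline. Of the called genes of the F-box and MATH list, 56 of 59 were higher. That list covers F-box, Skp1-related, BTB, BATH and MATH proteins, among them ubiquitin ligase adaptors. Heat-shock genes and cuticle collagens were mostly lower, and the heat-shock genes went the opposite way to the soma comparison. In the germline comparison, 555 genes had an adjusted p under 0.05 in the authors' deposited table, 369 higher and 186 lower (66.5% higher, exact two-sided binomial p = 6.4e-15). At an absolute log2 fold change of at least 1, there were 437 genes, 311 higher and 126 lower (exact binomial p = 3.9e-19).

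The germline control means stood apart from the other groups for many of these genes. The control mean was farther from the soma control mean than the depleted mean was in 233 of the 311 higher genes and in 105 of the 126 lower genes (exact binomial p = 4.4e-19 and 1.3e-14). In the soma comparison, the corresponding numbers were 72 of 242 higher and 50 of 242 lower genes. All genes were read from the same libraries, so the p-values above do not measure whether the control group differs beyond the spread between replicates.

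Of 59 called genes of the F-box and MATH list, 56 were higher and 3 lower (Fisher's exact p = 5.9e-08, adjusted p = 7.1e-07 over 12 lists). The Skp1-related genes skr-8 (chromosome IV, 17165250 to 17165834), skr-12 and skr-10 had log2 fold changes of 1.93, 1.91 and 1.84, and bath-10 had 1.61, in the authors' deposited table. For skr-8 the authors' deposited table gave 13.2 FPKM in germline controls, 50.2 after germline depletion, and 57.3 and 49.5 in the soma control and soma-depleted groups. The family median was 1.82 FPKM in germline controls and 4.71, 5.23 and 5.22 in the germline-depleted, soma control and soma-depleted groups in the authors' deposited table. Many of these genes have close copies, so counts of single members are uncertain, and the list test counts them as independent.

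All 10 listed heat-shock genes were lower after germline depletion (Fisher's exact p = 1.5e-05, adjusted p = 6.1e-05 over 12 lists). They made up 8 of the 10 largest negative log2 fold changes in the authors' deposited table, with hsp-16.48 (-1.95), hsp-70 (-1.84), hsp-16.41 (-1.80), F44E5.5 (-1.68), hsp-16.1 (-1.64), F44E5.4 (-1.61), hsp-16.2 (-1.58) and hsp-16.49 (-1.58). For hsp-16.41 (chromosome V, 1805178 to 1805875) the authors' deposited table gave 47 FPKM in soma controls, 145 in soma-depleted worms, 494 in germline controls and 142 in germline-depleted worms. The pairs hsp-16.1 and hsp-16.11, hsp-16.48 and hsp-16.49, and F44E5.4 and F44E5.5 are near-identical copies that can share reads. C18H7.1 (-1.61) and Y106G6D.4 (-1.58) completed the 10 largest negative values in the authors' deposited table.

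**Figure D1:**
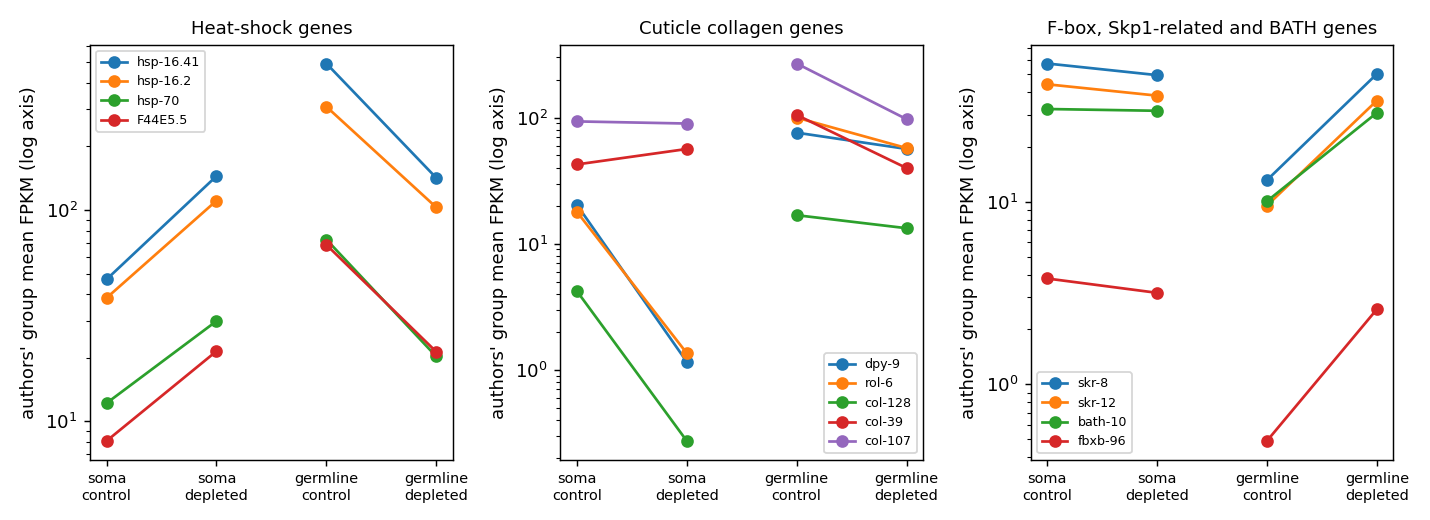
Authors' group mean FPKM (log axis, no replicate values, hence no error bars) of named heat-shock, cuticle and F-box, Skp1-related or BATH genes in the 4 groups, with lines joining the control and depleted means of each tissue. For hsp-16.41 the germline control mean of 494 FPKM is the highest of the 4, and for skr-8 the germline control mean of 13.2 FPKM is the lowest.

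Of 46 called cuticle genes, 15 were higher and 31 lower after germline depletion (Fisher's exact p = 1.0e-06, adjusted p = 6.2e-06 over 12 lists). The collagen genes col-107 (log2 fold change -1.46), col-39 (-1.40), col-12 (-1.39) and col-147 (-1.11) were lower in the authors' deposited table. The median over these 46 genes was 84.4 FPKM in germline controls and 41.7, 20.7 and 20.7 FPKM in the germline-depleted, soma control and soma-depleted groups in the authors' deposited table.

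Genes known by a sequence name led the increases in the authors' deposited table, namely C45B2.8 (log2 fold change 3.98), T09F5.20 (2.95) and Y116A8C.19 (2.63), together with the chemoreceptor gene str-31 (3.06), the lectin gene clec-196 (2.44), fbxb-96 (2.38) and the T-box transcription factor gene tbx-7 (2.29). Y54G2A.36 (chromosome IV, 2897694 to 2901651) had the smallest adjusted p, 5.7e-111, with 36.3 FPKM in controls and 192 after germline depletion in the authors' deposited table. The checkpoint kinase gene chk-2 (log2 fold change 1.24) and the pro-apoptotic gene egl-1 (1.15) were the 2 called genes of the DNA damage list, both higher in the authors' deposited table (Fisher's exact p = 0.554, adjusted p = 0.830). The germline-depleted mean of chk-2 (6.08 FPKM) was above its soma control mean (2.34), and that of egl-1 (3.69) was below (4.05). The histone gene his-67 (-1.18) was lower in the authors' deposited table. Of 18 called innate immunity genes, 10 were higher and 8 lower (Fisher's exact p = 0.320, adjusted p = 0.670), with fipr-26 at 1.87, thn-1 at -1.14 and fipr-7 at -1.07 on the log2 scale in the authors' deposited table. Of 12 called detoxification genes, 8 were higher and 4 lower (Fisher's exact p = 1), including sdz-28 (1.55), sdz-27 (1.08), ugt-13 (-1.33) and sdz-24 (-1.17) in the authors' deposited table. Of 8 called neuropeptide and insulin genes, 4 went each way (Fisher's exact p = 0.451), with ins-2 at 1.75, nlp-81 at -1.10, and nlp-12 at -1.07 on the log2 scale in the authors' deposited table. The neuropeptide gene nlp-14 had 93.4 FPKM in controls and 46.6 after depletion in the authors' deposited table. The 4 called sperm genes, spe-11 (1.24), msp-55 (1.22), msp-36 (1.27) and nspd-2 (0.81), were higher in the authors' deposited table (Fisher's exact p = 0.306, adjusted p = 0.670). C53A5.9 (1.66), vit-3 (0.58) and unc-119 (0.47) were also higher in the authors' deposited table.

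The soma and germline calls were then set side by side. Of 198 genes called in both comparisons, 142 went the same way (71.7%, exact two-sided binomial p = 8.4e-10), 69 higher and 73 lower. The other 56 went opposite ways, 33 higher in the soma and lower in the germline comparison and 23 the reverse. Strain genotype differed together with depletion in both comparisons, so a matching direction may reflect either. The 10 shared genes ranked first by the larger of their adjusted p-values were 8 heat-shock genes, including hsp-16.11 (log2 fold changes 1.24 and -1.54), with sdz-24 (-1.39 and -1.17) and F14D2.19 (-1.13 and -0.80), for soma and germline in the authors' deposited table. With an absolute log2 fold change of at least 1 in both comparisons, 39 genes were left and the share with the same direction, 64.1%, no longer passed (exact binomial p = 0.108).

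**Figure D2:**
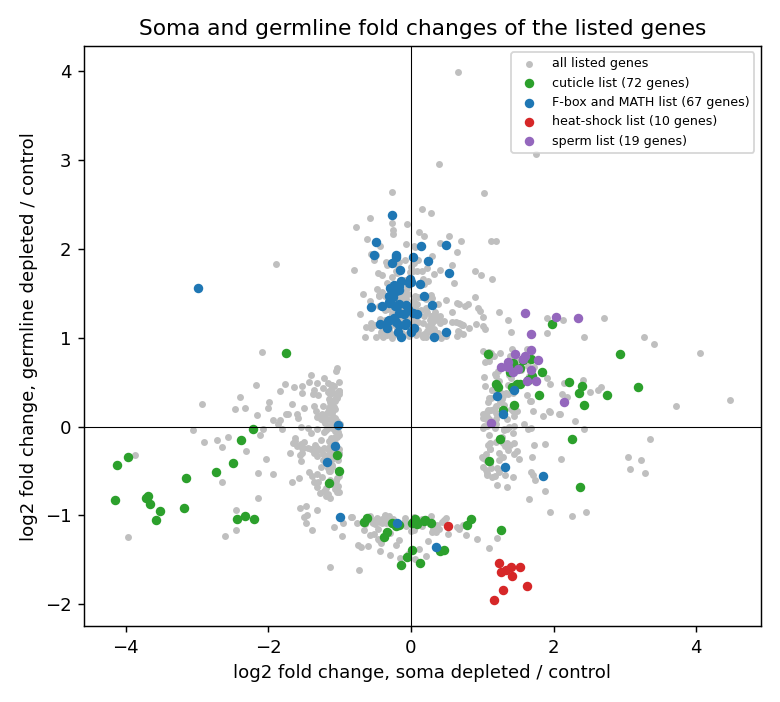
Log2 fold change (depleted over control) in the soma (x axis) and the germline (y axis) for the 882 listed genes, 1 point per gene, with 4 lists in colour. The center is empty because genes are listed only at an absolute log2 fold change of at least 1 in either comparison; the 10 heat-shock genes lie at the lower right and the 19 sperm genes at positive soma values.

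Splicing was the second readout. Alternative 3 prime splice sites, the acceptor ends of introns, were the most frequent type of called event in both tissues, and most differences at these sites had a negative sign. The authors' deposited table gives an inclusion level difference per event, but the sources used here do not state which group was subtracted from which, so signs are given as deposited. After soma depletion, 1606 events had a q-value under 0.05 in the authors' deposited table. They were 997 alternative 3 prime splice sites (A3SS), 283 retained introns (RI), 176 skipped exons (SE), 140 alternative 5 prime splice sites (A5SS) and 10 mutually exclusive exons (MXE). Of the A3SS events, 923 were negative and 74 positive (92.6% negative, 95% Wilson interval 90.8 to 94.0, exact two-sided binomial p = 2.4e-187). Of the SE events, 121 were negative and 55 positive (exact binomial p = 7.2e-07), and of the RI events 121 and 162 (exact binomial p = 0.0173, adjusted p = 0.0288 over 5 types). The RI split did not pass with an event counted once per gene (44.3% negative, exact binomial p = 0.0682), nor the SE split among 32 events at an absolute difference of at least 0.3 (56.2% negative, exact binomial p = 0.597). The splits of A5SS and MXE events did not pass, with 78 negative of 140 (exact binomial p = 0.205) and 5 of 10 (exact binomial p = 1).

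In the germline comparison, 796 events had a q-value under 0.05 in the authors' deposited table, made up of 437 A3SS, 150 RI, 109 SE, 89 A5SS and 11 MXE events. Of the A3SS events, 375 were negative and 62 positive (85.8% negative, 95% Wilson interval 82.2 to 88.8, exact binomial p = 1.2e-55). At an absolute difference of at least 0.3, only 33 germline A3SS events were left and the lean no longer passed (60.6% negative, exact binomial p = 0.296). The median A3SS difference was -0.170 in the soma and -0.102 in the germline in the authors' deposited table. The splits of the other types did not pass in the germline, with exact binomial p = 0.568 for RI, 0.702 for SE, 0.832 for A5SS and 0.549 for MXE.

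**Figure D3:**
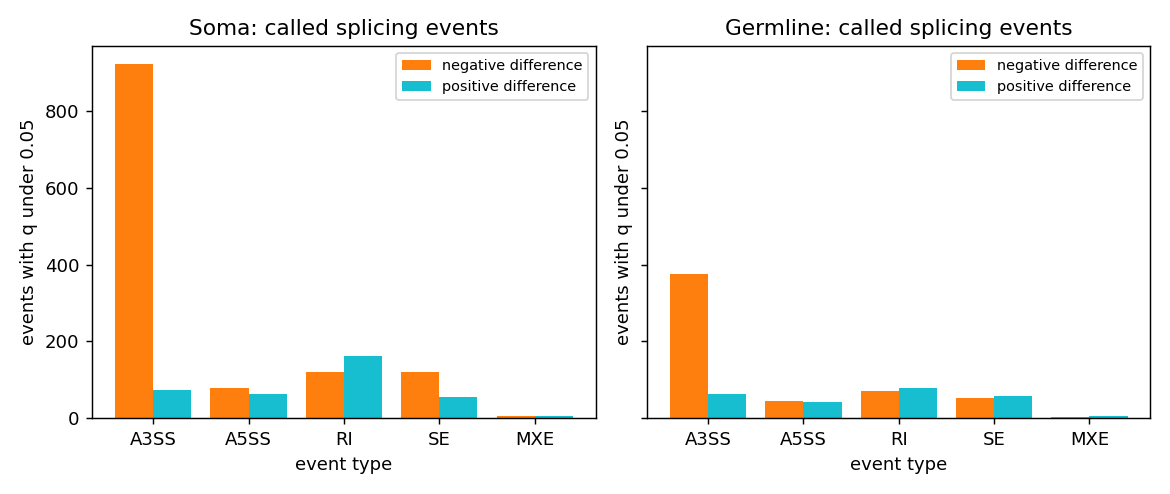
Number of called splicing events (q under 0.05) by event type in the soma and the germline, with negative and positive inclusion level differences as separate bars. Negative A3SS events are the tallest bar in each panel, at 923 and 375.

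Large A3SS differences in the soma were those of T16G12.9 (chromosome III, 10077480 to 10077652, coding, -1), F22B5.5 (chromosome II, 8453828 to 8453966, coding, 0.871) and C13C4.6 (chromosome V, 12122972 to 12123089, coding, -0.852) in the authors' deposited table. Among A5SS events, the lectin gene clec-149 (-1), F45H10.5 (0.890) and the chemoreceptor gene sru-39 (-0.651) had the largest soma differences in the authors' deposited table. Skipped exons with the largest differences were in the fibrillin-like gene fbn-1 (chromosome III, 7637356 to 7637496, coding, 0.930), the giant muscle protein gene unc-22 (-0.590) and the inositol trisphosphate receptor gene itr-1 (-0.586) in the authors' deposited table. Exons of fbn-1 (-0.509 and -0.390) and itr-1 (-0.474) also led the MXE events in the authors' deposited table. Retained introns were led by C16C8.13 with C16C8.12 (-0.713), Y6G8.2 (0.70) and fbxb-83 with its neighbours (-0.677) in the authors' deposited table. The reads behind each event are unknown, so the largest differences in either tissue may rest on few reads.

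In the germline, the sex determination gene xol-1 (chromosome X, 8043397 to 8044409, coding and 3 prime UTR, 0.612), the potassium channel gene twk-14 (-0.555) and sra-36 (-0.503) had the largest A3SS differences in the authors' deposited table. Among retained introns, bud-31, which encodes a spliceosome component, had a difference of 0.670 at chromosome III, 9696123 to 9696517, in the 5 prime UTR, followed by fbxb-83 (0.667) and F26D2.3 (0.667) in the authors' deposited table. The largest A5SS differences were in srx-74 (0.723), an unnamed gene model (-0.550) and F19C7.3 (-0.549) in the authors' deposited table. SE events were led by B0244.4 (0.843), srv-13 (-0.689) and T05A8.2 (0.667), and MXE events by srh-2 (0.342 and 0.294) and lgx-1 (-0.312), in the authors' deposited table.

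Event types were distributed differently between the soma and the germline comparison (permutation p = 0.00424, 100000 permutations). A3SS events made up 62.1% of soma and 54.9% of germline events (Fisher's exact p = 7.8e-04, adjusted p = 0.00392 over 5 types). The shares of the other types did not pass, at 8.72% and 11% for A5SS, 11% and 13.7% for SE, 17.6% and 18.8% for RI, and 0.623% and 1.38% for MXE. At an absolute difference of at least 0.2, those of A5SS, RI and SE did pass (Fisher's exact tests, adjusted p = 0.0210, 0.0198 and 0.00229). Events called in both tissues overlap in this test, so its p-values are approximate.

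At identical coordinates, 236 events were called in both tissues, and 207 of them had the same sign (87.7%, exact binomial p = 2.6e-34 against an even split). As differences leaned negative in both tissues, independent signs would already match in 78.1% of these events, and the signs went together beyond that (Fisher's exact p = 2.1e-08). A3SS events made up 206 of the 236, with 184 negative in both, 7 positive in both and 15 of opposite sign (92.7% the same, against 86.9% for independent signs, Fisher's exact p = 5.5e-06). These Fisher's exact tests were added after the signs had been seen. Of 24 shared RI events, 14 had the same sign (exact binomial p = 0.541). The shared events with the largest mean absolute differences had opposite signs in soma and germline in the authors' deposited table, namely fbxb-83 with its neighbours (-0.677 and 0.667), T01D3.3 (-0.597 and 0.528), F35E12.13 with F35E12.6 (-0.499 and 0.591), the ammonium transporter gene amt-2 (0.628 and -0.461) and twk-14 (0.454 and -0.555). Whether these signs rest on few reads was not tested. At an absolute difference of at least 0.2 in both tissues, 28 events were left and 57.1% had the same sign (exact binomial p = 0.572).

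The alternative 3 prime sites lay close together. For 745 of 871 soma A3SS events with an assigned strand, the annotation holds a shorter exon that shares the other edge, and in 659 of these (88.5%, 95% Wilson interval 86 to 90.6) its acceptor lay within 18 bases downstream. The distance was 6 bases in 237 events and 9 bases in 170. In the germline, 261 of 311 events (83.9%, 95% Wilson interval 79.4 to 87.6) lay within 18 bases, and the difference from the soma did not pass (Fisher's exact p = 0.0551). For A5SS events, 23 of 78 in the soma and 15 of 56 in the germline lay within 18 bases, a lower share than for A3SS (Fisher's exact p = 5.1e-29 and 4.3e-17). Among A3SS events called between sperm-producing and oocyte-producing worms of another study, 701 of 768 (91.3%) lay within 18 bases, 302 of them at 6 bases and 168 at 9. Among A5SS events called there, 26 of 94 (27.7%) did, so the lower A5SS share was not particular to SACY-1 depletion. Some of the events in that comparison were also called after SACY-1 depletion.

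**Figure D4:**
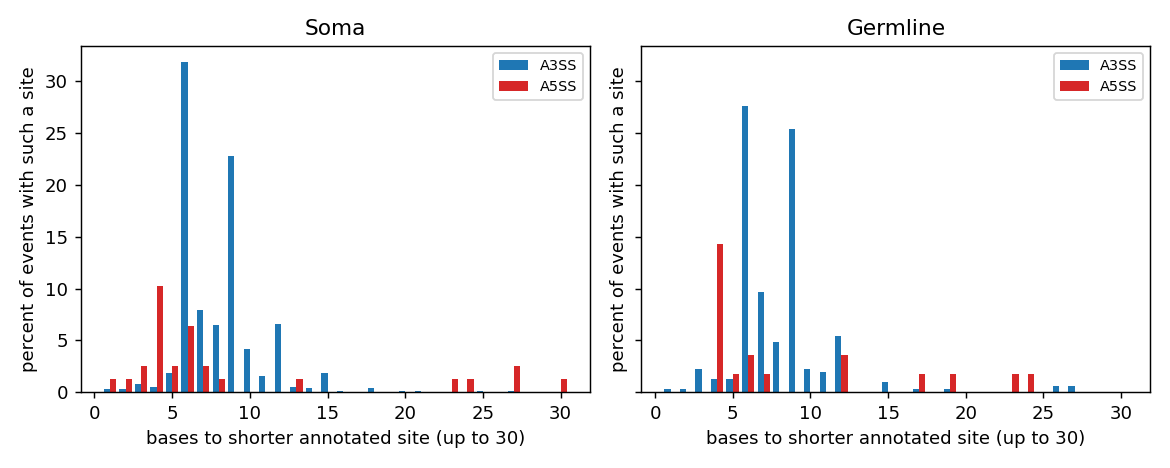
Distance in bases from the listed splice site to the nearest annotated shorter site (x axis, up to 30) as a percent of A3SS or A5SS events with such a site (y axis), for soma and germline. Soma A3SS events peak at 6 bases (237 events) and 9 bases (170 events).

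Some genes were called in both readouts; without the unchanged genes, no expected overlap could be computed. In the soma, 37 of 525 called genes also had a called splicing event, 21 higher and 16 lower (Fisher's exact p = 0.400 against the other called genes). Among them, abt-2, a lipid transporter gene, had a log2 fold change of 1.23 and an A3SS difference of -0.494, and the nuclear receptor gene nhr-71 had 1.44 and -0.458, in the authors' deposited table. In the germline, the number was 19 of 555, 15 higher and 4 lower (Fisher's exact p = 0.325). Y54G2A.36 was among them, with a log2 fold change of 2.41 and an RI difference of -0.185, as was T05A7.13, with 1.78 and 0.427, in the authors' deposited table. These 4 genes were chosen after their values were seen.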

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

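The test of A3SS events called in neither tissue was set before its result was seen; the other tests in this part were chosen after the result each measures was seen. The tests of the difference between tissues treat genes and events called in both tissues as independent.

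The heat-shock list went opposite ways, with 9 of 9 called genes higher after soma depletion and 10 of 10 lower after germline depletion (Fisher's exact p = 1.1e-05 for the difference). Reads shared within the near-identical pairs are argued against as the only source. Of the 4 members outside such pairs, 3 (hsp-16.2, hsp-16.41 and hsp-70, but not hsp-110) were also called in opposite directions. Whether these members share reads with other members of the list was not tested. All 10 genes had their highest mean in germline controls, and 0 of 10 had a germline-depleted mean below the soma control mean; a germline control group that stands high, through strain or handling, and a decrease through germline depletion would both give this order and cannot be told apart, since strain and depletion differ together. A high germline control group would leave open the higher values after soma depletion, where the median of the 9 called genes went from 16.3 to 36.6 FPKM in the authors' deposited table.

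The F-box and MATH list differed between tissues (56 higher and 3 lower in the germline, 5 and 5 in the soma, Fisher's exact p = 0.00102), and so did the split of all genes at a 2-fold change (311 of 437 against 242 of 484 higher, Fisher's exact p = 5.5e-11). Among all 311 higher germline genes at a 2-fold change, the control mean was farther from the soma control than the depleted mean in 74.9%; a low germline control group and an increase through depletion towards the soma level would both give this, and cannot be told apart. Fewer embryos in the germline control worms could be the source: 100% of the 15 called members of a list of genes transcribed in early embryos had their lowest mean in germline controls, the most abundant being sdz-27 (123 FPKM against 253 to 295) and skr-7 (15.5 against 42.9 to 72.6) in the authors' deposited table. That list does not decide, since it was compiled after vet-1, skr and sdz genes had been seen to be low there. Of its 58 genes, only the 15 called in the germline comparison were counted. A gene called higher there already has its control mean below its depleted mean, and the share over all such genes is not given here. Moreover, 9 of the 15 also belong to another list, and the list left out sdz-24, sdz-3 and sdz-29. Of the 8 called sdz genes, 6 were lowest in germline controls, but sdz-24 (388 FPKM against 94.9 to 248) and sdz-3 (3.23 against 1.56 to 2.95) were highest there in the authors' deposited table, and an effect of depletion remains open.

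A3SS differences were mostly negative, more so in the soma than in the germline (92.6% against 85.8%, Fisher's exact p = 1.2e-04). Small differences as the source are argued against for the soma, where 93.2% of 251 events stayed negative at an absolute difference of at least 0.3. For the germline they stay open, with 60.6% of 33 events, and the read depth behind events, low for lowly expressed genes, was not tested in either tissue. An asymmetry of the caller or of read mapping could not be excluded or borne out: 74.9% of 382 A3SS events called in neither tissue were negative in the soma (95% Wilson interval 70.3 to 79.0), between the bounds of 85% and 70% set beforehand. Those events were listed because they differed between sperm-producing and oocyte-producing worms, so they may also hold weaker changes of the same kind. As their signs were taken from the soma comparison only, the test cannot tell such an asymmetry from weaker changes after soma depletion. The signs of A3SS events in the sperm and oocyte comparison itself are not given here.

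Cuticle genes split differently between the comparisons, with 33 higher and 22 lower in the soma and 15 and 31 in the germline (Fisher's exact p = 0.00906). The median of the 46 genes called in the germline was highest in germline controls, at 84.4 FPKM, in the authors' deposited table. A high germline control group and a decrease through germline depletion cannot be told apart here either. Negative SE differences made up 121 of 176 soma and 52 of 109 germline events (Fisher's exact p = 4.8e-04). The share of A3SS among called events differed between tissues (Fisher's exact test, adjusted p = 0.00392). Of the listed events, 930 were called only in the sperm and oocyte comparison of another study's reads; A3SS events among them entered the test of events called in neither tissue and the site distances.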

How the results depend on the processing

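Of 205 alternative values, 149 stayed on their side of the threshold or, without a test, within 1.5 times (counts) or the 95% interval (shares). Another 44 moved beyond these limits, 8 fell short of the threshold, 4 newly passed it and 0 passed in the opposite direction. Some splits that did not pass changed direction. At an absolute difference of at least 0.2, the negative share went from 55.7% to 39.7% for soma A5SS and from 47.7% to 54.05% for germline SE events. At 0.3, it went from 47.3% to 52.4% for germline RI events. Counts fell under stricter limits because fewer genes or events can pass; the cause of other shifts was not tested. At an absolute log2 fold change of at least 2, chosen after seeing the data, 82 soma and 29 germline genes were left. Requiring the germline-depleted mean to lie beyond both soma means, also chosen after seeing the data, left 195 germline genes. With a mean count of at least 100, the soma share higher was 44.7% (exact binomial p = 0.0478). A mean count of at least 10 removed no gene, so it tests nothing. Genes called in both comparisons numbered 113 at adjusted p under 0.01 and 39 at a 2-fold change in both, where 64.1% went the same way. Soma events numbered 721 and 417, and germline events 220 and 114, at absolute differences of at least 0.2 and 0.3; 402 germline events passed at q under 0.01. The share of negative differences lost its test for soma RI events at 0.2 (45.1%), at 0.3 (43%) and counted once per gene (44.3%), and at 0.3 for soma SE (56.3%), germline A3SS (60.6%) and all germline events (56.1%). At 0.2, type shares newly differed between tissues for A5SS (adjusted p = 0.0210), RI (0.0198) and SE (0.00229, Fisher's exact tests), against a range over the other settings of 0.0821 to 0.0824, 0.464 to 0.818 and 0.0824 to 0.0946. Events shared at 0.2 in both tissues numbered 28, with 57.1% of the same sign, and genes in both readouts numbered 24 in the soma and 9 in the germline. The share of sites within 18 bases was 90.8% for soma A3SS, 45.8% for soma A5SS and 72.7% for germline A3SS at 0.2. No paired analysis was possible because the tables give comparisons and group means without replicate values; for the same reason edgeR, DESeq2, TMM scaling, no count filter, leaving out each replicate and a replicate block were not run. Depth per sample is unknown, so what depth limits could not be assessed.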

Other observations

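All observations in this part were chosen after the data were seen. In the germline-depleted group, 17 called genes had a mean at least 2-fold above each of the other 3 groups and 6 a mean at least 2-fold below. Those above included Y54G2A.36, with 192 FPKM against 36.3 to 52.2 in the other groups, ZK970.7, with 97.6 FPKM against 22.8 to 34.1, and F40G9.20, with 476 FPKM against 113 to 207, in the authors' deposited table. T24B8.5, an innate immunity gene, was also among them, with 150 FPKM against 42 to 65.5 in the authors' deposited table. Those below included his-67, ugt-13 and clec-75. More genes were set apart by the germline control mean, which stood at least 2-fold above each other group in 56 called genes and below in 177. For the soma control mean and genes called in the soma, the numbers were 16 and 31. In the soma-depleted group, 72 called genes stood at least 2-fold above each other group and 123 at least 2-fold below. Besides the collagens, those below included the tubulin gene tba-8, with 0.866 FPKM against 5.65 to 13.4, and the esterase gene cest-1, with 22.3 FPKM against 50.3 to 65.5, in the authors' deposited table.

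A3SS events called in 1 comparison leaned the same way in the other. Of 767 events called only in the soma and measured in the germline, 497 were negative and 259 positive there, with a median of -0.014 against -0.175 in the soma. Of 229 called only in the germline, 151 were negative and 74 positive in the soma, with a median of -0.014. A3SS events called in neither tissue were also mostly negative in the soma (286 of 382). The lean therefore does not by itself show a change shared between the soma and the germline depletion. SE events called only in the soma had 88 negative and 81 positive values in the germline.

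Outside the fixed lists, nuclear hormone receptor genes were the only name family with at least 8 called members, with 7 higher and 2 lower after soma depletion, which did not differ from other called genes (Fisher's exact p = 0.106).

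The strain marker unc-119 was called higher in 2 of 2 comparisons, and its retained-intron event (chromosome III, 10907780 to 10908927, coding and 3 prime UTR) had differences of 0.043 in the soma and 0.066 in the germline in the authors' deposited table. The control strains carry unc-119(ed3) and the depleted strains do not list it, so genotype and depletion cannot be separated for this gene, and neither was tested.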
